A study of Callithrix jacchus with 8 samples.

How the data were processed

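Total RNA was taken from marmoset embryonic stem cells (line cj367) collected with Accutase at 80% confluency, purified with RNeasy and made into libraries with a BGI kit for mRNA (Optimal Dual-mode), per the labels. There were 8 libraries in 4 groups of 2 biological replicates, named primed euploid, PLAXA euploid, PLAXAW euploid and PLAXAW aneuploid, and each library was assigned to its group by its title. The submitters' processing notes name Bowtie2 2.4.5 and RSEM 1.3.1 without the role of each. The genome build, the annotation and the strand setting are not stated.

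The authors deposited expected counts per gene, which are estimated read counts with decimals and no normalization, in 1 column per library. The authors also deposited TPM values, which are scaled for transcript length and sum to the same total in every library. The count table held 23751 genes, of which 4350 carried XLOC names and 19397 NCBI gene numbers, and 4 had no value. In the reference, 18862 of those numbers were found, and 220 LOC names were replaced by its symbols. Library totals ran from 5553544 to 14497393 counts. XLOC genes took 9.44% to 12.0% of the counts, LOC genes 6.22% to 6.49%, and the 10 genes with the most counts 4.20% to 6.56%.

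Expected counts were rounded, genes were filtered with filterByExpr by group, and 18223 genes were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM scaling. All 8 libraries entered 1 fit with 1 coefficient per group and no other term, so that groups of 2 share an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The 4 comparisons were PLAXA euploid against primed, PLAXAW euploid against primed, PLAXAW euploid against PLAXA euploid, and PLAXAW aneuploid against PLAXAW euploid. The groups, comparisons, tests, naming rule, gene lists and most alternatives were set before the data were examined. Replicate numbers were not treated as pairs, because the labels do not say that a number marks a shared batch. The difference of replicate 1 and replicate 2 did not correlate between groups (-0.03 to 0.01 across genes).

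Of 35 gene lists, 33 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and adjusted over the lists. A list of the embryo at genome activation had too few tested members, and none of the mitochondrial genome was in the table. Some genes are in several lists, so the lists are not separate evidence. Among them are DPPA3 (naive and germ cell), NODAL (naive and NODAL-activin), KLF4 and TFCP2L1 (naive and LIF-STAT3) and HAND1 (trophoblast, amnion and mesoderm). The same tests were applied to 23 groups of genes on a chromosome (14186 tested genes). Chromosome numbers follow symbols in the files that name the chromosome of an open reading frame and were carried over to the chromosomes of the reference assembly, which served for names and gene order only.

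Named genes were set by rule. They were the 5 called genes with the largest rise and the 5 with the largest fall that had a symbol, at least 5 CPM in the higher group and no overlap between replicates, up to 3 called members of each list past its test and of the naive, primed and core lists, and a fixed panel of markers. Of the largest changes, P3H3, PROSER3, SZT2, PTPRN2, DNAJC24, CHTF18 and ACIN1 were left out of the text after their values were seen, because counts of 0 in some libraries beside a high level in others may reflect how reads were assigned, and other genes that the rule names were left out for length. Genes that a sentence says were chosen after their values were seen lie outside it. CPM used TMM-scaled totals, and log2 CPM a prior count of 2. A fold against a group at 0 is a lower bound over a floor of 3 counts in the group, and a fold against 1 to 3 counts is given with an exact binomial interval. Genes kept in the text at 0 in a group, such as ARAP3, CLIC6, CAPSL, BECN2 and FAM53B, are open to the doubt about read assignment as well.

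The alternatives were DESeq2 1.42.0, relative log expression factors, library totals, no low-count filter, a stricter filter, a fold of at least 2, only the libraries of both groups, a term for the replicate number, each library left out, and limma-trend on TPM with a pseudocount of 1, of 0.1, or with no filter. Thinning all libraries to the smallest total was added after the data were seen. A group left with 1 library was assumed to vary like the others. Other splits of the libraries were not counted, since groups of 2 are too small.

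The test was also tested on simulated data with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. In PLAXA against primed libraries it recovered 19.4%, 37.3% and 63.6% of them, in PLAXAW against primed 14.9%, 32.8% and 51.5%, in PLAXAW against PLAXA 19.4%, 34.3% and 60.6%, and in aneuploid against euploid PLAXAW 13.4%, 40.3% and 57.6%. These changed genes were a small share of those tested, whereas 4754 to 10512 genes were called in the deposited data. The adjusted threshold was therefore stricter in the simulation, and these shares do not give the sensitivity of the real comparisons. XIST was not in the table.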

Results

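Cultures of common marmoset embryonic stem cells (line cj367) were compared by bulk RNA-seq in 4 groups of 2 biological replicates. Primed cells resemble the epiblast after implantation, and naive cells resemble the epiblast before it. The naive cells were kept in either of the culture conditions named PLAXA and PLAXAW, and the PLAXAW cells came as a euploid group and as a group described as wholly aneuploid. Estimated counts summed to 11197300 and 14497393 in the primed libraries, 5795600 and 5553544 in PLAXA, 9007230 and 9138335 in euploid PLAXAW, and 14214332 and 14171714 in aneuploid PLAXAW. Across genes, log2 normalized counts (CPM) of the replicates correlated at r = 0.964 in primed, 0.931 in PLAXA, 0.952 in euploid PLAXAW and 0.976 in aneuploid PLAXAW libraries, where genes are not independent replicates. The first principal component held 48.4% of the variance and set the primed libraries, at 153 and 156, apart from the naive libraries, at -25.4 to -64.4.

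Changes are log2 fold changes from edgeR ± standard error (SE) with n = 2 libraries per group, and levels are mean CPM ± SD of those libraries. The edgeR test reports no SE, so the SE was calculated as the absolute change divided by the square root of its F statistic. For genes with few counts in a group, such as DCN, SPRY4 and SUSD2, this SE can be smaller than counting error alone. It does not measure the precision of those changes. The p-values rest on the spread between biological replicates. Lower bounds and count intervals cover counting error only. The values are RSEM estimates, the genome build, annotation and strand setting are not stated, and so reads that similar genes share may have been assigned to either of them.

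**Figure D1:**
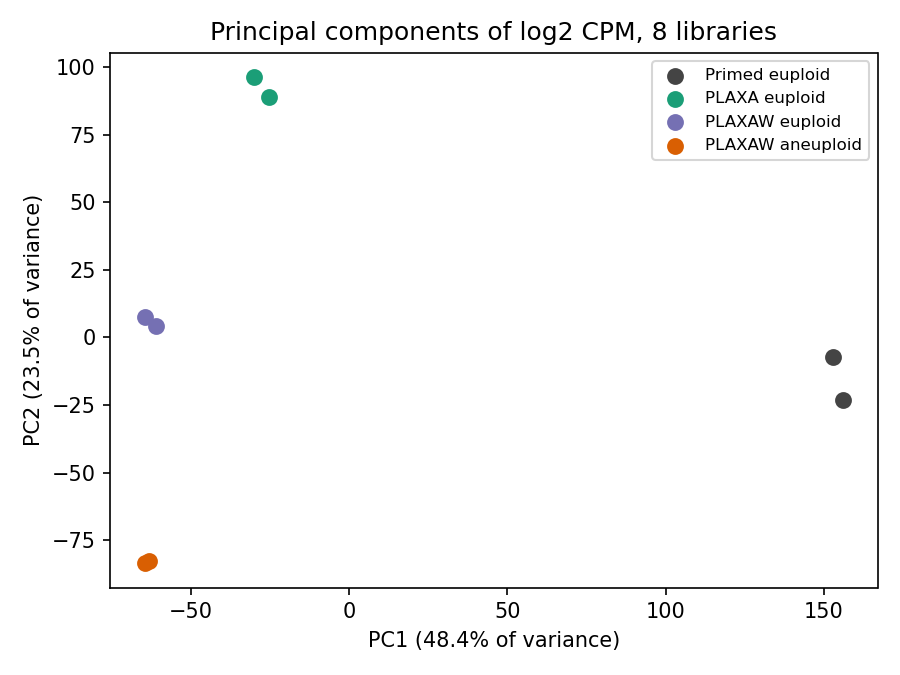
Principal component scores of the 8 libraries from log2 CPM, with the first component (48.4% of the variance) on the horizontal axis and the second (23.5%) on the vertical axis, 1 point per library, coloured by group. The primed libraries lie at 153 and 156 on the first component, and the aneuploid PLAXAW libraries lie at -82.8 and -83.5 on the second, away from the euploid PLAXAW libraries at 4.11 and 7.64.

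In PLAXA, genes of the naive state stood far above their level in primed cells. KLF17 (NCBI gene 100413697), a transcription factor of the naive epiblast, was at 58.9 ± 2.19 CPM (SD, n = 2) in PLAXA and at 0 in primed cells, which makes it at least 542-fold higher over a floor of 3 counts in the group. SUSD2 (100395754), a surface marker of naive cells, rose from 0.231 ± 0.146 to 142 ± 3.25 CPM, by 9.27 ± 0.18 (edgeR, adjusted p = 5.4e-07). The feedback inhibitor of ERK signalling DUSP6 (100409879) fell from 459 ± 26.3 to 5.84 ± 1.36 CPM, a change of -6.29 ± 0.13 (adjusted p = 9.32e-07). The collagen gene COL3A1 (100394494) rose from 61.6 ± 24.3 to 6816 ± 537 CPM, by 6.80 ± 0.29 (adjusted p = 9.18e-06).

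Of the 21 measured genes in the naive pluripotency list, 20 rose, none fell and ALPP was not called (camera, adjusted p = 1.91e-70, 0.0202 with an estimated correlation), and 20 rose when adjusted over the list alone. The list's median change was 6.91, or 4.05 with the 6 members at 0 in primed cells set to their bound. DPPA5, a naive marker, rose by 7.75 ± 0.20, KLF4 by 5.09 ± 0.08 and TFCP2L1, a transcription factor of the naive network, by 3.87 ± 0.12. DNMT3L, a cofactor of DNA methylation, was at 7.57 ± 0.05 CPM and at 0 in primed cells, at least 69.7-fold higher. The small protein DPPA3, of germ cells and early embryos, rose by 6.91 ± 0.08. Genes that primed cells express went the other way, and in the primed list 14 fell, 5 rose and 2 were not called, both over all genes and adjusted over the list alone. The median was -1.51 (adjusted p = 2.5e-07, adjusted p = 0.102 with an estimated correlation). The epiblast transcription factors ZIC2 and OTX2 changed by -2.27 ± 0.08 and -1.69 ± 0.14, and the WNT inhibitor SFRP2 by -2.22 ± 0.05.

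The general pluripotency factors POU5F1, SOX2 and NANOG moved little, while other genes of the core list moved more. POU5F1 was not called (-0.02 ± 0.05, edgeR, adjusted p = 0.768), SOX2 fell by 0.31 ± 0.07 (adjusted p = 0.0101) and NANOG rose by 0.54 ± 0.07 (adjusted p = 0.000974). The core pluripotency list had 7 genes that rose, 3 that fell and 5 not called, the same when adjusted over the list alone. The median was 0.54 (camera, adjusted p = 0.00127, adjusted p = 0.102 with an estimated correlation, and 0.0632 without primed replicate 1, in a range of 0.000506 to 0.102 with camera, and 3.7e-05 with fry). GDF3, a ligand of the NODAL pathway, rose most among its named genes, by 4.54 ± 0.11. The DNA methyltransferase gene DNMT3B, a member of the primed list, rose by 0.76 ± 0.18 (adjusted p = 0.0117), against the direction of that list.

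Signalling and stress genes shifted as well. In the FGF-ERK list 11 fell, 3 rose and 7 were not called, with 12 that fell when adjusted over the list alone. The median was -0.67 (camera, adjusted p = 6.27e-07, adjusted p = 0.072 with an estimated correlation). The ERK inhibitor gene SPRY1 changed by -5.52 ± 0.31. In the proteasome list 29 of 31 genes rose, 0 fell and 2 were not called, 29 when adjusted over the list alone. The median was 0.65 (adjusted p = 2.35e-09, adjusted p = 0.301 with an estimated correlation), and PSMC6, a proteasome subunit gene, rose by 1.08 ± 0.05. In the cytosolic heat shock list 12 rose, 0 fell and 3 were not called, 12 when adjusted over the list alone. The median was 0.67 (adjusted p = 2.5e-07, adjusted p = 0.0804 with an estimated correlation), and the chaperone gene HSP90AA1 rose by 2.05 ± 0.03. In the ATF4 amino acid response list 14 rose, 4 fell and 3 were not called, the same adjusted over the list alone. The median was 1.23 (adjusted p = 3.96e-07, adjusted p = 0.0804 with an estimated correlation), with DDIT4, an inhibitor of mTOR, up by 3.68 ± 0.15. In the chromosome segregation list 20 fell, 3 rose and 10 were not called, with 21 that fell when adjusted over the list alone. The median was -0.38 (adjusted p = 0.00484, adjusted p = 0.44 with an estimated correlation), and the mitotic activator gene CDC20 changed by -1.69 ± 0.06.

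Among lists of other lineages, the fibroblast, endoderm and germ cell lists were higher in PLAXA. The germ cell list had 7 that rose, 0 that fell and 6 not called, the same adjusted over the list alone (camera, adjusted p = 9.11e-05, adjusted p = 0.0804 with an estimated correlation). In the fibroblast list 13 rose, 3 fell and 4 were not called, the same adjusted over the list alone. The median was 2.61 (camera, adjusted p = 0.000943, adjusted p = 0.354 with an estimated correlation). In the hypoblast and endoderm list 9 rose, 3 fell and 5 were not called, with 11 that rose when adjusted over the list alone. The median was 0.73 (adjusted p = 0.000943, adjusted p = 0.124 with an estimated correlation), and GATA4, a transcription factor of the hypoblast, rose by 7.53 ± 0.14. OGN, a proteoglycan of connective tissue, was at 129 ± 0.66 CPM against 0 in primed cells, at least 1190-fold higher. BECN2, a relative of an autophagy gene, was at least 236-fold higher. The trophoblast, amnion, mesoderm and neural ectoderm lists did not pass (camera, adjusted p = 0.384, 0.233, 0.187 and 0.187). In them 7, 5, 5 and 4 genes rose, 3, 2, 1 and 1 fell and 7, 5, 9 and 3 were not called, with 8, 6, 5 and 4 that rose when adjusted over the list alone. The neural list did pass without aneuploid replicate 1 (0.0486) or 2 (0.0494) and with only the libraries of both groups (0.0304), in a range of 0.0304 to 0.353 with camera, and 0.000206 with fry. ARAP3, a regulator of small GTPases, fell from 115 ± 11.5 CPM to 0, at least 403-fold lower, and CLIC6, a chloride channel gene, from 97.0 ± 17.9 CPM to 0, at least 342-fold lower.

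In all, 9993 of the 18223 genes tested were called between PLAXA and primed cells (edgeR), 4877 higher and 5116 lower in PLAXA, 48.8% of them higher. That share was 36% with library totals, which moved the median over all genes from -0.102 to -0.309, and 32.5% with limma-trend on log2(TPM + 1), and 5499 genes also changed at least 2-fold. Without PLAXA replicate 2 the call of SOX2 was lost (adjusted p = 0.0595, range 0.000902 to 0.0595 over its alternatives), DNMT3B lost its call without PLAXA replicate 1 (0.0574), without primed replicate 1 (0.0556), and with log2(TPM + 0.1) (0.0514) or unfiltered TPM (0.0687), in a range of 1.23e-05 to 0.0687, and POU5F1 was called lower with library totals (0.00746, range 0.00129 to 0.948).

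**Figure D2:**
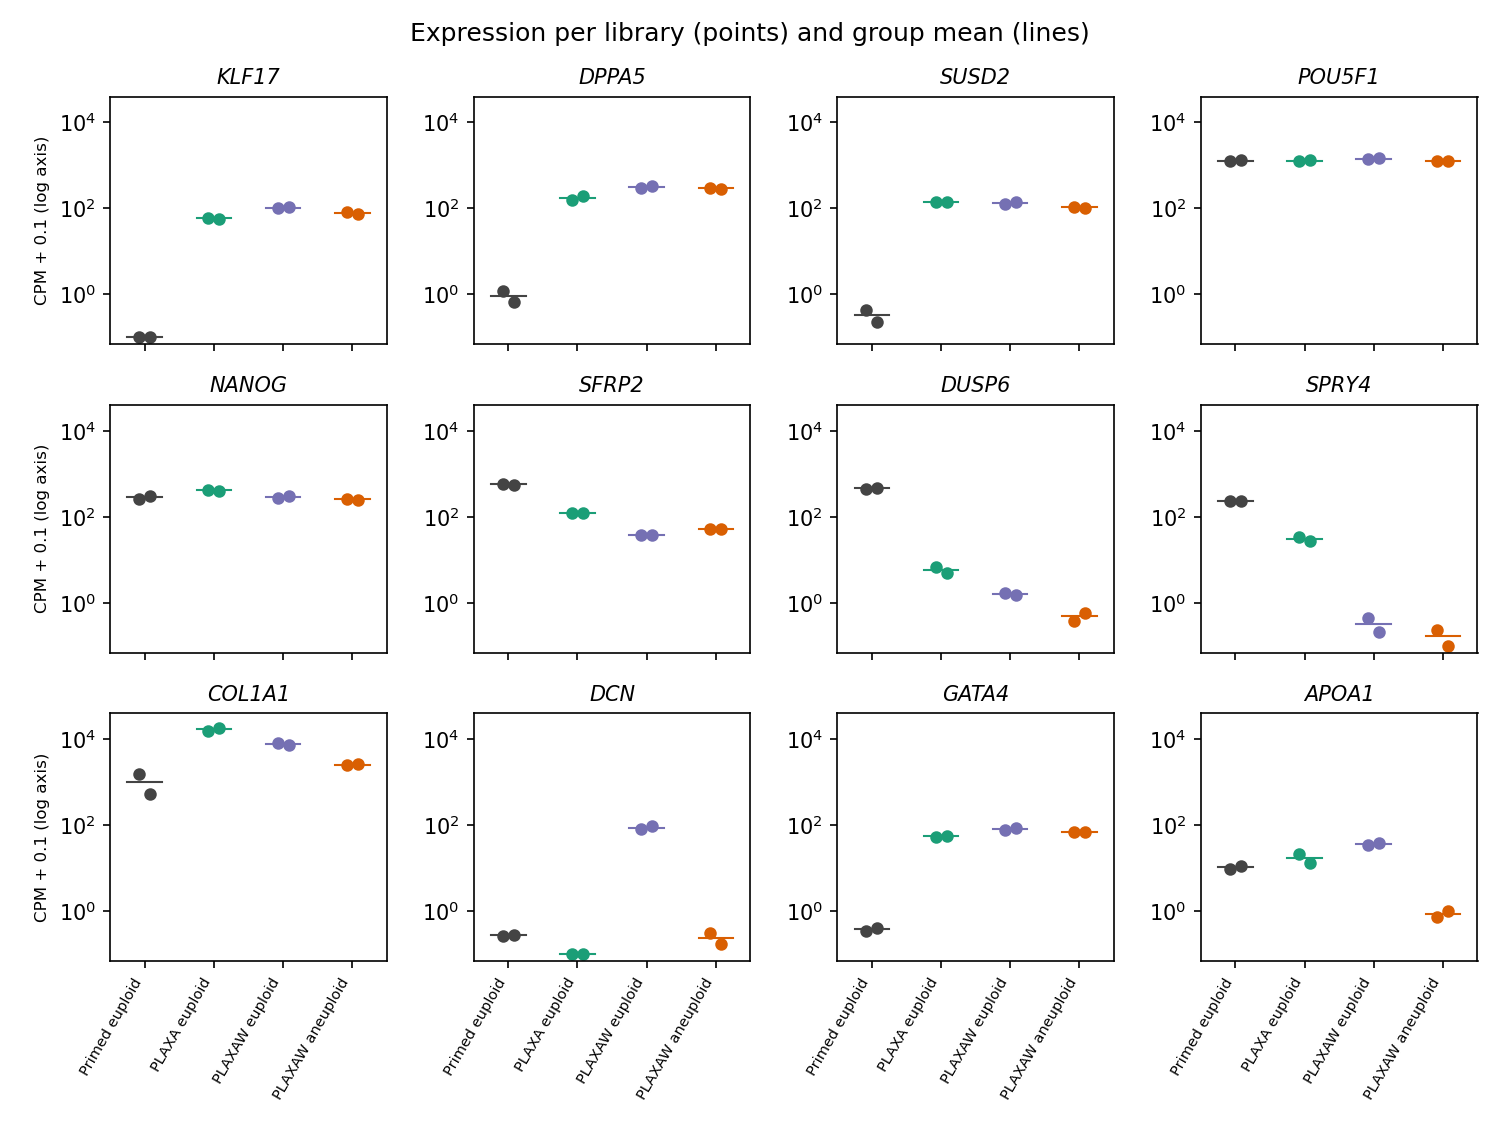
CPM + 0.1 per library on a log axis for 12 of the named genes, 1 point per library, coloured by group, with a line at each group mean. KLF17 stands at 0 CPM in the primed libraries and at 58.9 CPM in PLAXA and 104 CPM in euploid PLAXAW on average.

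Against primed cells, PLAXAW cells rose in the same naive genes and fell further in ERK targets. KLF17 was at 104 ± 4.12 CPM (SD, n = 2) against 0, at least 954-fold higher, and ZSCAN4 (100896427), a gene of the embryo at genome activation, was at 75.5 ± 0.18 CPM against 0, at least 696-fold higher. SPRY4 (100391285), an inhibitor of ERK signalling, fell from 233 ± 5.60 to 0.224 ± 0.159 CPM, a change of -9.95 ± 0.30 (edgeR, adjusted p = 1.49e-06). CDKN1A (100894215), a cell cycle inhibitor that p53 induces, rose from 6.87 ± 1.87 to 89.5 ± 1.52 CPM, by 3.72 ± 0.16 (adjusted p = 6.02e-06).

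All 21 genes of the naive list rose, also when adjusted over the list alone. The median was 8.03 (or 6.04 with members at 0 set to their bound, camera, adjusted p = 7.47e-74, 0.0144 with an estimated correlation). SUSD2 rose by 9.20 ± 0.18, DPPA5 by 8.62 ± 0.19, KLF4 by 5.06 ± 0.08 and TFCP2L1 by 3.78 ± 0.12, and DNMT3L was at least 99.7-fold higher. In the FGF-ERK list 16 fell, 0 rose and 5 were not called, 16 when adjusted over the list alone. The median was -2.35 (adjusted p = 1.2e-16, 0.0144 with an estimated correlation), and DUSP6 changed by -8.24 ± 0.15. In the primed list 15 fell, 5 rose and 1 was not called, the same adjusted over the list alone. The median was -2.44 (adjusted p = 1.58e-10, adjusted p = 0.0612 with an estimated correlation), with ZIC2 at -3.50 ± 0.08, OTX2 at -2.42 ± 0.15 and SFRP2 at -3.94 ± 0.06. POU5F1 rose by 0.14 ± 0.05 (adjusted p = 0.0447) but was -0.11 and not called with the 3 TPM settings (adjusted p = 0.0693 to 0.111, in a range of 0.0197 to 0.743). SOX2 changed by -0.30 ± 0.07 (adjusted p = 0.0107), and NANOG (0.02 ± 0.07, adjusted p = 0.801) and DNMT3B (0.25 ± 0.18, adjusted p = 0.271) were not called. With the 3 TPM settings NANOG was called lower, at -0.23 (adjusted p = 0.0227 to 0.0336, in a range of 0.0227 to 0.961).

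The amnion, endoderm, germ cell and fibroblast lists were higher in PLAXAW than in primed cells, and the trophoblast list did not pass. All 12 genes of the amnion list rose, also when adjusted over the list alone. The median was 3.14 (or 2.97 at the bounds, camera, adjusted p = 8.1e-05, adjusted p = 0.0612 with an estimated correlation), and the mesoderm and amnion transcription factors HAND1 and ISL1, both at 0 in primed cells, were at least 107-fold and at least 33.4-fold higher. In the hypoblast and endoderm list 10 rose, 2 fell and 5 were not called, the same adjusted over the list alone. The median was 1.69 (adjusted p = 2.27e-05, adjusted p = 0.0612 with an estimated correlation), with GATA4 up by 8.12 ± 0.13. In the germ cell list 8 rose, 0 fell and 5 were not called, with 8 that rose and 1 that fell when adjusted over the list alone. The median was 2.69 (camera, adjusted p = 1.06e-05, adjusted p = 0.0612 with an estimated correlation), and DPPA3, also in the naive list, rose by 7.97 ± 0.08. In the fibroblast list 15 rose, 4 fell and 1 was not called, the same adjusted over the list alone. The median was 2.28 (adjusted p = 0.00602, adjusted p = 0.527 with an estimated correlation), and the matrix proteoglycan gene DCN rose by 8.85 ± 0.26. The trophoblast, mesoderm and neural ectoderm lists had 11, 9 and 5 genes that rose, 4, 1 and 1 that fell and 2, 5 and 2 not called, the same adjusted over the list alone (camera, adjusted p = 0.28, 0.129 and 0.401), and the mesoderm list passed without primed replicate 1 (0.0385), in a range of 0.0385 to 0.324 with camera, and 0.000377 with fry.

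Targets of p53 and of ATF4 rose too. In the p53 list 16 rose, 2 fell and 4 were not called, with 17 that rose when adjusted over the list alone. The median was 0.92 (camera, adjusted p = 4.21e-05, adjusted p = 0.0548 with an estimated correlation), and MDM2, a p53 target and regulator, rose by 2.52 ± 0.11. In the ATF4 list 16 rose, 3 fell and 2 were not called, the same adjusted over the list alone. The median was 1.61 (adjusted p = 4.49e-10, adjusted p = 0.0548 with an estimated correlation), with STC2, a secreted stress protein, up by 5.71 ± 0.28. In the NODAL-activin list 6 rose, 2 fell and 2 were not called, with 7 that rose when adjusted over the list alone. The median was 0.90 (camera, adjusted p = 5.68e-06, adjusted p = 0.0548 with an estimated correlation), and NODAL itself, also in the naive list, rose by 5.25 ± 0.09. MIOX, an enzyme of inositol breakdown with 1 count in the primed libraries, was at 246 ± 18.0 CPM, a ratio of 6800 with an exact binomial 95% interval of 1220 to 269000. CAPSL, a calcium-binding protein gene, fell from 14.0 ± 0.09 CPM to 0, at least 83.8-fold lower. The p53 and NODAL-activin lists also passed as higher in PLAXA against primed cells, with 13 and 5 that rose and 5 and 3 that fell. Their adjusted p-values were 0.0114 and 0.000259 (camera, 0.122 and 0.0804 with an estimated correlation). Both passed as higher in PLAXAW against PLAXA too (camera, adjusted p = 0.00165 and 0.00793, 0.116 and 0.138 with an estimated correlation). In that comparison the p53 list had 10 that rose, 1 that fell and 11 not called, with a median of 0.33. The NODAL-activin list had 4 that rose, 1 that fell and 5 not called, and its median was 0 beside a mean of 0.77. Most of its genes were thus not higher.

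Between PLAXAW and primed cells 10512 genes were called (edgeR), 5294 higher and 5218 lower in PLAXAW, 50.4% of them higher, against 36.1% with limma-trend on log2(TPM + 1). POU5F1 kept its call in only 5 of 19 alternatives (adjusted p from 0.0197 to 0.743), with 0.743 under library totals, 0.159 without primed replicate 1, 0.148 without PLAXAW euploid replicate 2, 0.0514 without PLAXA replicate 1, and 0.0734 and 0.0747 without aneuploid replicate 1 and 2, and SOX2 lost its call without PLAXAW euploid replicate 2 (0.0712) and without primed replicate 2 (0.0516), in a range of 5.84e-05 to 0.0712.

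Genes that changed in both comparisons with primed cells mostly moved the same way. Between them, 7669 genes were called in the same direction, 3833 higher and 3836 lower, where independent sets of the same sizes would share 1417 and 1465. Both comparisons used the same primed libraries, so part of the excess may come from those shared controls. In 10 simulations of groups that did not differ, no gene was called against the shared controls, so the simulated overlap of 0 does not measure their part. A further 212 genes were called in opposite directions.

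PLAXAW cells had lower ERK targets and higher cholesterol synthesis genes than PLAXA cells. SPRY4 fell from 30.8 ± 5.25 to 0.224 ± 0.159 CPM (SD, n = 2), a change of -7.04 ± 0.36 (edgeR, adjusted p = 0.000102). INSIG1 (100397040), a sterol-responsive regulator of cholesterol synthesis, rose from 24.3 ± 2.90 to 54.2 ± 1.90 CPM, by 1.16 ± 0.10 (adjusted p = 0.000541). DCN (100405391) was at 89.0 ± 9.89 CPM in PLAXAW and at 0 in PLAXA, at least 314-fold higher, and LUM, another matrix proteoglycan, was at least 69.6-fold higher.

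In the FGF-ERK list 15 fell, 0 rose and 6 were not called, with 16 that fell when adjusted over the list alone. The median was -1.32 (camera, adjusted p = 4.65e-15, 0.0271 with an estimated correlation). The ERK-responsive transcription factors ETV5 and EGR1 changed by -3.44 ± 0.28 and -2.25 ± 0.21. In the cholesterol synthesis list 19 of 20 rose, 0 fell and 1 was not called, with 20 that rose when adjusted over the list alone. The median was 0.63 (adjusted p = 4.15e-14, adjusted p = 0.0806 with an estimated correlation), and the sterol demethylase gene CYP51A1 rose by 1.01 ± 0.08. In the autophagy and lysosome list 13 rose, 1 fell and 7 were not called, with 14 and 2 when adjusted over the list alone. The median was 0.64 (adjusted p = 4.72e-07, adjusted p = 0.119 with an estimated correlation), and CTSB, a lysosomal protease, rose by 1.54 ± 0.07.

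In the naive list 12 rose, 1 fell and 8 were not called, with 13 that rose when adjusted over the list alone. The median was 0.86 (camera, adjusted p = 3.72e-11, adjusted p = 0.0583 with an estimated correlation). KLF17 rose by 0.81 ± 0.07 and DPPA5 by 0.86 ± 0.11, whereas SUSD2 (-0.07 ± 0.09, adjusted p = 0.601), TFCP2L1 (-0.09 ± 0.10, adjusted p = 0.54), KLF4 (-0.02 ± 0.06, adjusted p = 0.8) and DNMT3L (0.52 ± 0.29, adjusted p = 0.233) were not called. In the primed list 11 fell, 4 rose and 6 were not called, with 12 that fell when adjusted over the list alone. The median was -0.73 (adjusted p = 0.000237, adjusted p = 0.198 with an estimated correlation), with SFRP2 at -1.72 ± 0.05, ZIC2 at -1.23 ± 0.09 and OTX2 at -0.73 ± 0.15 (adjusted p = 0.0144). NANOG fell by 0.52 ± 0.07 (adjusted p = 0.00331), and POU5F1 (0.16 ± 0.05, adjusted p = 0.05), SOX2 (0.02 ± 0.07, adjusted p = 0.897) and DNMT3B (-0.51 ± 0.18, adjusted p = 0.0786) were not called.

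Among lists of other lineages the amnion, endoderm and germ cell lists passed as higher in PLAXAW. The amnion list was higher, with 9 that rose, 1 that fell and 2 not called, and 2 that fell when adjusted over the list alone. The median was 2.51 (or 2.43 at the bounds, camera, adjusted p = 1.7e-05, adjusted p = 0.0806 with an estimated correlation). IGFBP3, a growth factor binding protein of that list with 1 count in PLAXA, was at 44.3 ± 3.45 CPM, a ratio of 469 with an exact binomial 95% interval of 83.9 to 18500. The hypoblast and endoderm list had 8 that rose, 1 that fell and 8 not called, with 9 and 2 when adjusted over the list alone. The median was 0.62 (adjusted p = 0.00793, adjusted p = 0.138 with an estimated correlation), and GATA6, a hypoblast transcription factor, rose by 1.26 ± 0.22. The germ cell list had 4 that rose, 0 that fell and 9 not called, the same adjusted over the list alone. The median was 0.3 (adjusted p = 0.0291, adjusted p = 0.198 with an estimated correlation), and it did not pass without PLAXA replicate 1 (0.0767), PLAXAW euploid replicate 2 (0.0588), primed replicate 1 (0.169) or primed replicate 2 (0.15), in a range of 0.00258 to 0.198 with camera, and 0.00108 with fry. The trophoblast, mesoderm and neural ectoderm lists did not pass (adjusted p = 0.768, 0.738 and 0.405), with 5, 3 and 2 that rose, 4, 1 and 3 that fell and 8, 11 and 3 not called, the same adjusted over the list alone. The fibroblast list, with 3 that rose, 8 that fell and 9 not called (12 that fell when adjusted over the list alone), did not pass its test (adjusted p = 0.166), though it passed with only the libraries of both groups (7.51e-05) and without primed replicate 1 (0.000433) or 2 (0.000298), in a range of 7.51e-05 to 0.664, and its median of -1 and mean of 0.13 differed in sign.

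Between PLAXAW and PLAXA 5547 genes were called (edgeR), 2866 higher and 2681 lower in PLAXAW, 51.7% of them higher against 62.5% with library totals, 43.7% with DESeq2 and 45.3% with relative log expression factors, and 3485 genes were called without PLAXAW euploid replicate 2. OTX2 lost its call without PLAXA replicate 1 (adjusted p = 0.0686), without PLAXAW euploid replicate 2 (0.0713) and with only the libraries of both groups (0.0782), in a range of 0.00261 to 0.0782, while POU5F1 was called higher with library totals (0.0109) and without PLAXAW euploid replicate 1 (0.032), primed replicate 1 (0.0349) or primed replicate 2 (0.035), in a range of 0.0109 to 0.195, and DNMT3B lower with DESeq2 (0.00434) and without PLAXA replicate 2 (0.0396), in a range of 0.00434 to 0.343.

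**Figure D3:**
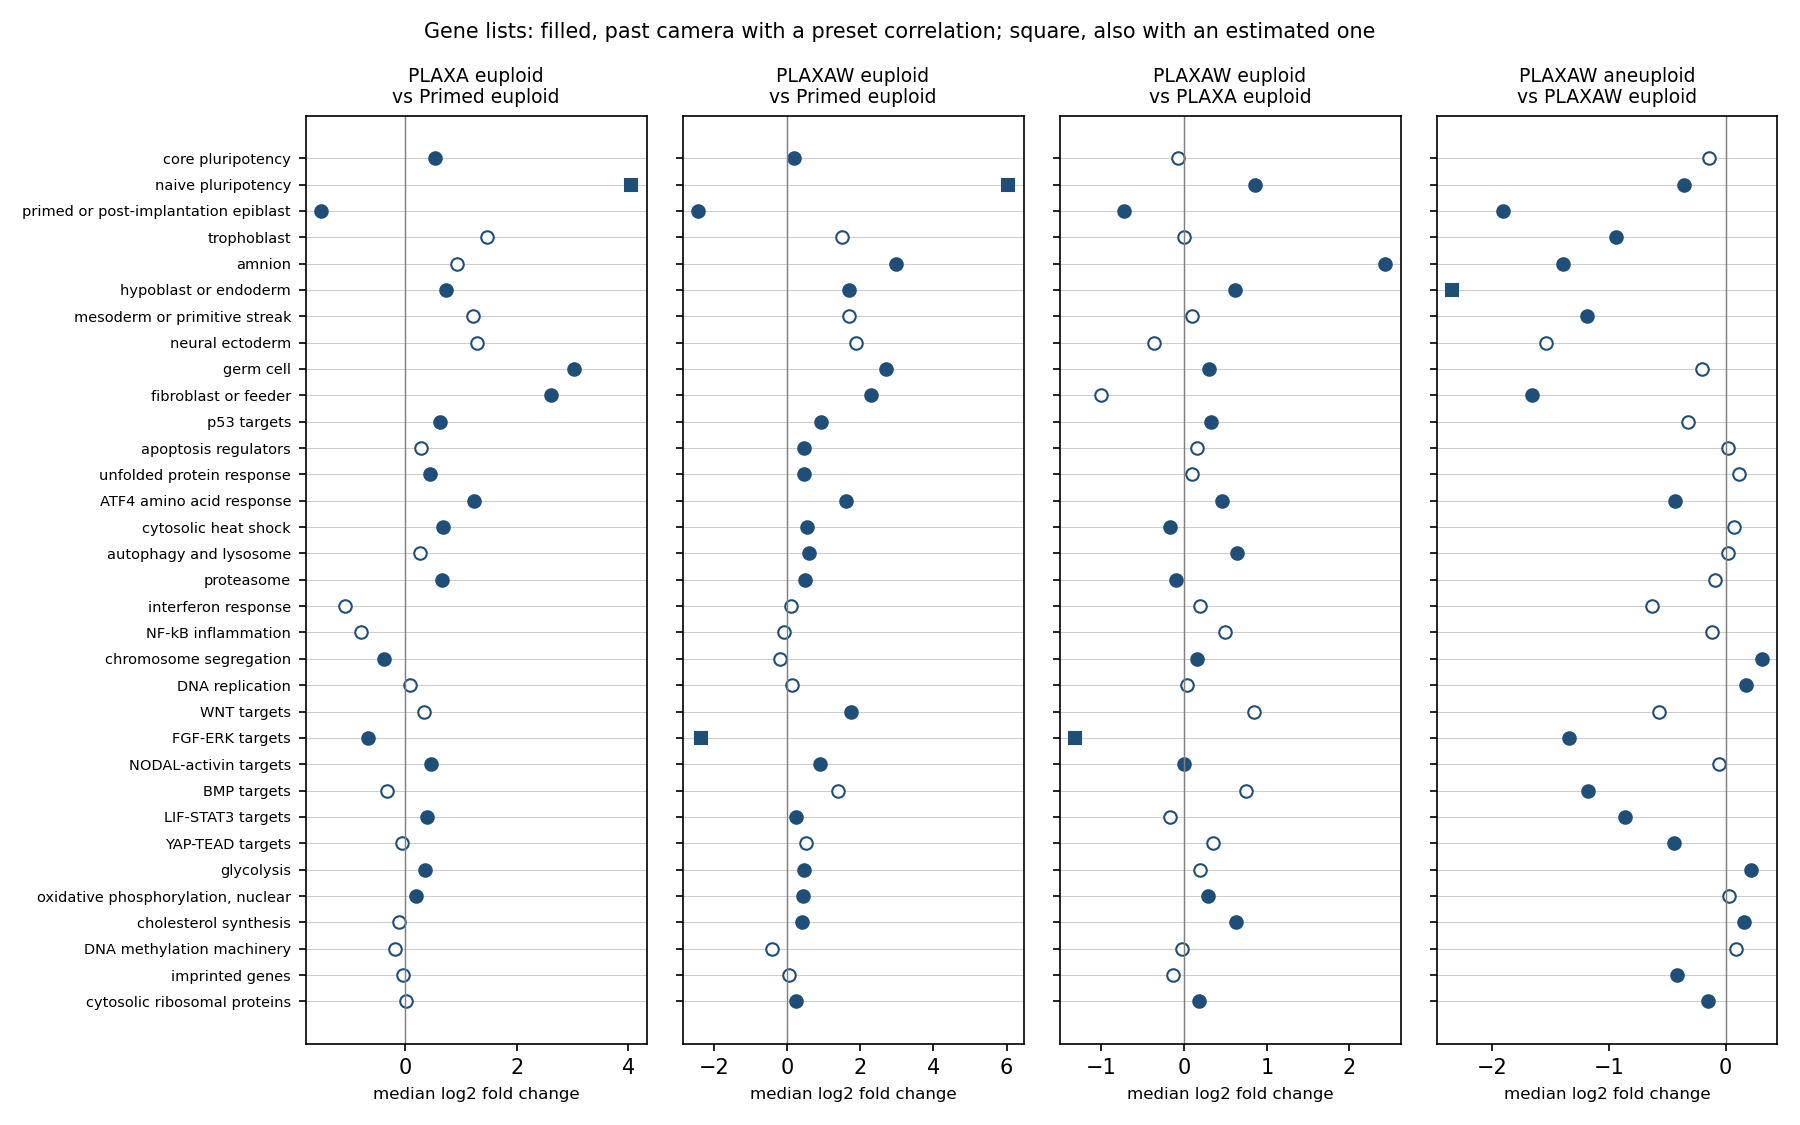
Median log2 fold change (horizontal axis, members at 0 in a group set to their bound) of each tested gene list in the 4 comparisons, with filled points for lists past camera with the preset correlation and squares for lists also past with an estimated one. The naive list lies at 4.05 and 6.04 in the comparisons with primed cells, and the hypoblast and endoderm list lies at -2.34 in aneuploid against euploid PLAXAW cells.

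Of the 33 gene lists tested, 17 passed camera in PLAXA against primed cells, 22 in PLAXAW against primed cells, 16 in PLAXAW against PLAXA and 18 in aneuploid against euploid cells, and 1, 2, 1 and 1 passed with an estimated correlation. Fry, which compares a list with no other genes, passed 28, 30, 25 and 26. The sign of the median depended on the scaling for lists that moved little. In PLAXA against primed cells these were autophagy, DNA replication, oxidative phosphorylation and ribosomal proteins, and in PLAXAW against primed cells core pluripotency, interferon, DNA replication, imprinted genes and ribosomal proteins. Between the naive conditions they were core pluripotency, trophoblast, DNA replication, NODAL-activin and DNA methylation, and in aneuploid against euploid cells germ cell, proteasome, NF-kB and NODAL-activin. The size of a median depended on the setting too. In aneuploid against euploid cells, log2(TPM + 1) gave the FGF-ERK list -0.43 against -1.34 with TMM. It gave the mesoderm list -0.5 against -1.19, the fibroblast list -1.45 against -1.66 and the chromosome segregation list 0.42 against 0.31.

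Aneuploid PLAXAW cells had lower endoderm and fibroblast genes than euploid PLAXAW cells. DCN fell from 89.0 ± 9.89 to 0.14 ± 0.10 CPM (SD, n = 2), a change of -9.20 ± 0.27 (edgeR, adjusted p = 4.57e-05), and LUM fell from 19.8 ± 0.04 CPM to 0, at least 188-fold lower. APOA1 (100386212), an apolipoprotein of endoderm, fell from 36.4 ± 2.86 to 0.769 ± 0.198 CPM, a change of -5.54 ± 0.33 (adjusted p = 0.000157). The kinetochore gene CENPE (100408237) rose from 56.9 ± 4.08 to 97.4 ± 6.40 CPM, by 0.78 ± 0.09 (adjusted p = 0.00191).

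In the hypoblast and endoderm list 15 of 17 genes fell, 0 rose and 2 were not called, 15 when adjusted over the list alone. The median was -2.34 (camera, adjusted p = 4.84e-19, 0.0249 with an estimated correlation). FOXA2, an endoderm transcription factor with 1 count in the aneuploid libraries, was higher in euploid cells by a ratio of 83 with an exact binomial 95% interval of 14.2 to 3340. The plasma protein genes GC and HABP2 were at 0 in aneuploid cells, at least 272-fold and at least 146-fold lower. In the fibroblast list 15 of 20 genes fell, 0 rose and 5 were not called, with 18 that fell when adjusted over the list alone. The median was -1.66 (adjusted p = 6.96e-17, adjusted p = 0.0965 with an estimated correlation), and the smooth muscle and fibroblast gene TAGLN changed by -3.42 ± 0.10. The growth factor genes GDF6 and INHBA were at 0 in aneuploid cells, at least 141-fold and at least 113-fold lower.

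Other cell-type lists fell too, among them the primed list, with 10 that fell, 3 that rose and 8 not called, and 11 and 4 when adjusted over the list alone. The median was -1.9 (camera, adjusted p = 1.44e-06, adjusted p = 0.0965 with an estimated correlation). The amnion, mesoderm and trophoblast lists had 6 genes each that fell, 0, 2 and 1 that rose and 6, 7 and 10 not called, with 7, 7 and 10 that fell and 1, 2 and 1 that rose when adjusted over the list alone. Their medians were -1.38, -1.19 and -0.94 (adjusted p = 0.000898, 0.00178 and 0.00467, adjusted p = 0.0965 with an estimated correlation for each). PDGFRA, a receptor gene of mesoderm and hypoblast, changed by -4.31 ± 0.16, and IGFBP3 by -6.28 ± 0.51. The neural ectoderm list (4 fell, 1 rose, 3 not called, 5 that fell when adjusted over the list alone, adjusted p = 0.144) passed only without aneuploid replicate 1 (0.0128) or 2 (0.0204) with camera, in a range of 0.0128 to 0.496, and with fry (0.000802), and the germ cell list (3 fell, 0 rose, 10 not called, the same adjusted over the list alone, adjusted p = 0.383) only with fry (0.00948).

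In the chromosome segregation list 17 rose, 1 fell and 15 were not called, with 19 that rose when adjusted over the list alone. The median was 0.31 (camera, adjusted p = 1.44e-06, adjusted p = 0.208 with an estimated correlation), and the kinetochore gene KNL1 and the chromosomal passenger gene BIRC5 rose by 0.74 ± 0.06 and 0.72 ± 0.11. In the DNA replication list 9 rose, 1 fell and 15 were not called, with 10 that rose when adjusted over the list alone. The median was 0.17 (adjusted p = 0.00526, adjusted p = 0.316 with an estimated correlation), with the polymerase gene POLA1 up by 0.46 ± 0.05. LIN28B, an RNA-binding protein of stem cells, rose by 0.77 ± 0.05, and HDGFL1, a growth factor relative, by 4.73 ± 0.40. FAM53B, a regulator of WNT signalling, was at 7.73 ± 2.03 CPM and at 0 in euploid cells, at least 46.2-fold higher.

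Of the signalling and response lists, several went down. In the LIF-STAT3 list 8 fell, 1 rose and 2 were not called, the same adjusted over the list alone. The median was -0.86 (camera, adjusted p = 5.08e-06, adjusted p = 0.0847 with an estimated correlation), with the receptor gene LIFR at -3.38 ± 0.29 and the feedback inhibitor gene SOCS3 at -1.62 ± 0.20. In the FGF-ERK list 12 fell, 1 rose and 8 were not called, with 13 that fell when adjusted over the list alone. The median was -1.34 (adjusted p = 1.52e-05, adjusted p = 0.0847 with an estimated correlation), and EGR1 changed by -4.04 ± 0.31. In the ATF4 list 12 fell, 1 rose and 8 were not called, with 13 that fell when adjusted over the list alone. The median was -0.43 (adjusted p = 4.15e-05, adjusted p = 0.0965 with an estimated correlation), and STC2 changed by -1.48 ± 0.20. The YAP-TEAD list (7 fell, 0 rose, 6 not called, the same adjusted over the list alone) and the BMP list (4 fell, 0 rose, 7 not called, 5 that fell when adjusted over the list alone) passed as lower. Their adjusted p-values were 0.00062 and 0.0169 (camera, adjusted p = 0.208 and 0.15 with an estimated correlation), and the BMP list did not pass with only the libraries of both groups (0.0708, in a range of 0.00763 to 0.15 with camera, and 0.000446 with fry). The WNT (4 fell, 0 rose, 11 not called), NODAL-activin (2 fell, 1 rose, 7 not called) and NF-kB (0 fell, 0 rose, 9 not called) lists, with the same counts adjusted over the list alone, did not pass (adjusted p = 0.226, 0.444 and 0.867, and 0.000634, 0.0138 and 0.093 with fry). In the imprinted list, which is not a signalling list, 5 fell, 2 rose and 8 were not called, the same adjusted over the list alone. The median was -0.41 (adjusted p = 0.00203, adjusted p = 0.0965 with an estimated correlation, and 0.0632 without PLAXAW euploid replicate 1, in a range of 0.000266 to 0.0965 with camera, and 0.000235 with fry), and the growth factor gene IGF2 changed by -3.52 ± 0.11.

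The p53, unfolded protein response and interferon lists did not pass camera in aneuploid cells. The p53 list had 1 that rose, 8 that fell and 13 not called, the same adjusted over the list alone. The median was -0.32 (camera, adjusted p = 0.0572, from 0.00942 to 0.2 over its camera alternatives, and past the threshold as lower without PLAXA replicate 2 (0.0444), PLAXAW euploid replicate 1 (0.0261), primed replicate 1 (0.0099) or primed replicate 2 (0.0124) and with fry (0.000428)), and neither CDKN1A (-0.27 ± 0.13, adjusted p = 0.188) nor MDM2 (-0.18 ± 0.10, adjusted p = 0.232) was called. The unfolded protein response list (6 rose, 4 fell, 7 not called, the same adjusted over the list alone, adjusted p = 0.212) passed as higher only with fry (0.00336), and its chaperone gene HSPA5 was not called (-0.08 ± 0.05, adjusted p = 0.316). The interferon list, with 1 that rose, 4 that fell and 9 not called (5 that fell when adjusted over the list alone), had an adjusted p of 0.157 and passed as lower only with fry (0.00351). GDF15 and ISG15, at most 2 and 3 counts in any library, were too low to test. The autophagy receptor gene SQSTM1 changed by -0.43 ± 0.10 (edgeR, adjusted p = 0.0261).

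In the naive list 9 fell, 2 rose and 10 were not called, with 10 and 3 when adjusted over the list alone. The median was -0.36 (camera, adjusted p = 0.0287, adjusted p = 0.2 with an estimated correlation, 0.0901 without aneuploid replicate 2 and 0.0618 with only the libraries of both groups, in a range of 0.0183 to 0.2 with camera, and 0.00115 with fry). KLF4 changed by -1.52 ± 0.06, DNMT3L by -2.14 ± 0.30 and KLF17 by -0.40 ± 0.07 (edgeR, adjusted p = 0.0119). POU5F1 (-0.14 ± 0.05, adjusted p = 0.0803), NANOG (-0.15 ± 0.07, adjusted p = 0.179) and SOX2 (-0.06 ± 0.07, adjusted p = 0.572) were not called. The primed list, given above, had a median of -1.9, with 10 that fell and 3 that rose (camera, adjusted p = 1.44e-06, 0.0965 with an estimated correlation). With limma-trend on log2(TPM + 1) the medians were -0.38 for the primed list and -0.23 for the naive list. No test compared both lists.

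Between aneuploid and euploid PLAXAW cells 4754 genes were called (edgeR), 2051 higher and 2703 lower in aneuploid cells, 43.1% of them higher against 60% with limma-trend on log2(TPM + 1), and 1924 also changed at least 2-fold, 386 higher and 1538 lower (20.1% higher). The count was 2984 without PLAXAW euploid replicate 2, 2105 without aneuploid replicate 1 and 2073 without aneuploid replicate 2. KLF17 lost its call without PLAXAW euploid replicate 2 (adjusted p = 0.0656) or aneuploid replicate 1 (0.0594) or 2 (0.0971) in a range of 0.000159 to 0.0971, SQSTM1 lost it without any 1 library of either group (0.0878 to 0.139, in a range of 0.000925 to 0.139), and CDKN1A was called lower without primed replicate 1 (0.0336) or 2 (0.0335) and with only the libraries of both groups (0.02), in a range of 0.02 to 0.605.

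Chromosome groups were tested as sets in all 4 comparisons, and 0 of the 23 passed in any of them (camera with the preset correlation). Unadjusted p-values under 0.05 were found for 0 groups in PLAXA against primed, 0 in PLAXAW against primed, 1 in PLAXAW against PLAXA and 6 in aneuploid against euploid cells. An estimated correlation gave 5 groups past the threshold in the last and 0 in the others, and fry, which tests whether genes move mostly 1 way and compares them with no other genes, gave 20, 19, 18 and 21. In aneuploid against euploid cells chromosome 1 had the highest median change, 0.12 over 1074 genes, with 230 that rose and 140 that fell (adjusted p = 0.106, and 0.0236 with an estimated correlation). The lowest was chromosome 8 at -0.14 (adjusted p = 0.106, and 0.0353 with an estimated correlation). Relative to the mean of the euploid PLAXAW libraries, the chromosome 1 median was 0.12 and 0.11 in the aneuploid libraries, -0.06 in both PLAXA libraries, and 0.009 and -0.04 in the primed libraries.

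**Figure D4:**
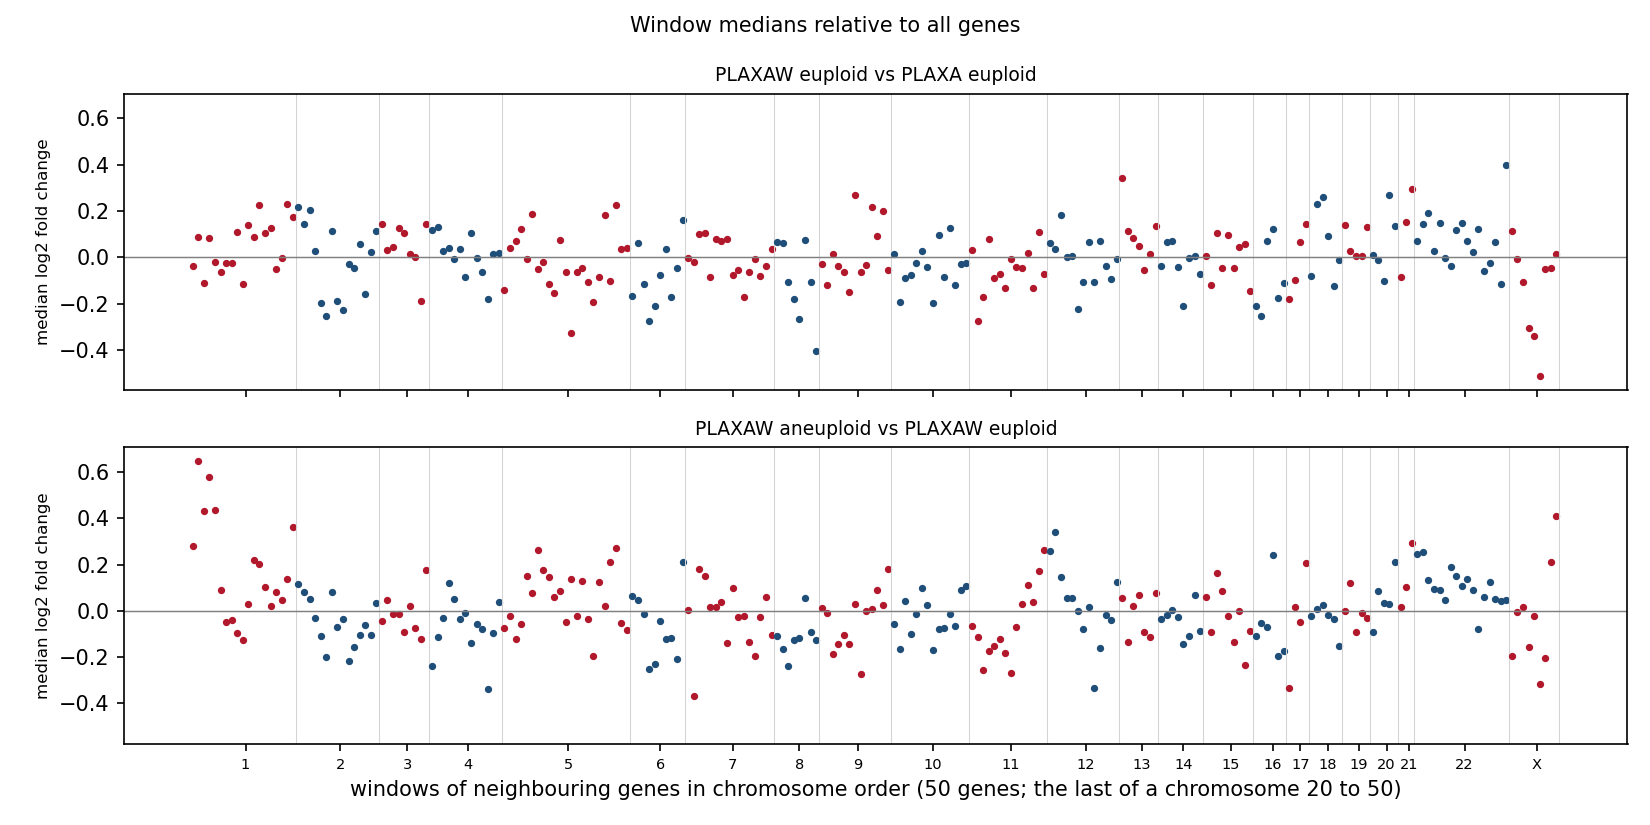
Median log2 fold change, relative to all genes, of windows of 50 neighbouring genes along the chromosome groups (horizontal axis, in gene order), in PLAXAW against PLAXA (top) and in aneuploid against euploid PLAXAW cells (bottom), 1 point per window. In the lower panel windows 2 to 5 of chromosome 1 lie at 0.65, 0.43, 0.58 and 0.44.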

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

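All tests of single genes in this part were chosen after their results were seen. The counts of opposite genes rest on the planned fits. Of the genes called in both comparisons with primed cells, 212 moved opposite ways in PLAXA and PLAXAW, and the difference between both effects, which is the comparison of PLAXAW with PLAXA, was called for all 212 (edgeR), as the selection of opposite calls against the same primed libraries nearly ensures. The 4 genes below had the largest differences among named genes with at least 1 CPM in PLAXA, at least 5 CPM in some group and replicates that did not overlap.

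SERPINE1, an inhibitor of plasminogen activation that TGF-beta induces, stood at 7.46 CPM in primed cells, 3.41 in PLAXA and 122 in PLAXAW (n = 2 each). Its changes against primed cells were -1.11 in PLAXA and 4.05 in PLAXAW, a difference of 5.15 ± 0.28 (SE, edgeR, adjusted p = 0.000134). HAPLN1, a linker of matrix proteoglycans, stood at 7.66, 1.98 and 52.3 CPM, with changes of -1.94 and 2.78 and a difference of 4.71 ± 0.23 (adjusted p = 9.35e-05). SCUBE3, a secreted signalling protein, stood at 9.86, 2.81 and 30.2 CPM, with changes of -1.80 and 1.62 and a difference of 3.41 ± 0.27 (adjusted p = 0.000454).

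NELL2, a secreted protein of neurons, went the other way, at 4.11 CPM in primed cells, 19.5 in PLAXA and 1.45 in PLAXAW. Its changes were 2.25 and -1.49, and the difference was -3.74 ± 0.51 (adjusted p = 0.00289). Groups of 2 libraries allow no test for a library far from its group, and no explanation of these differences was tested.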

How the results depend on the processing

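The thinning of all libraries to the smallest total was chosen after the data were seen, and the other alternatives before. For single named genes, 3331 of the values under other settings kept their direction and side of the threshold, 99 lost and 13 gained a call, and 23 changed direction. With 1 library left out these numbers were 2166, 147, 6 and 9. For gene lists they were 788, 84, 42 and 10 under other settings and 997, 30, 15 and 14 with 1 library left out. The cause was not tested except where a setting itself gives it.

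Counts of called genes stayed within 1.5 times under other settings except for the fold of at least 2, which gave 5499 in PLAXA and 5862 in PLAXAW against primed cells, 1910 in PLAXAW against PLAXA, 1924 in aneuploid against euploid cells and 3912 genes shared between both comparisons with primed cells, and which removes small changes by construction. The replicate block gave 9292, 9897, 4697, 4006 and 7039. With 1 library left out, 3485 to 5285 genes were called between PLAXAW and PLAXA, with the lowest count without PLAXAW euploid replicate 2. In aneuploid against euploid cells 2073 to 4774 were called, with 2984 without PLAXAW euploid replicate 2, 2105 without aneuploid replicate 1 and 2073 without aneuploid replicate 2. An estimated correlation left 1, 2, 1 and 1 lists past the threshold in the 4 comparisons in turn, and fry gave 28 in PLAXA against primed cells and 25 in PLAXAW against PLAXA. No chromosome passed camera with the preset correlation, 5 passed with an estimated correlation in aneuploid against euploid cells, and fry, which compares with no other genes, gave 20, 19, 18 and 21 (unadjusted camera p under 0.05 for 0, 0, 1 and 6).

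Single named genes that changed direction follow. In PLAXA against primed cells POU5F1 was 0.005 with DESeq2 and relative log expression factors, 0.019 with only both groups' libraries and -0.067 to 0.018 with a library left out. In PLAXAW against primed cells POU5F1 was -0.11 with the 3 TPM settings, and NANOG was -0.005 with DESeq2 and relative log expression factors, -0.099 with library totals, -0.228, -0.229 and -0.228 with TPM (called, adjusted p = 0.0227, 0.0253 and 0.0336, in a range of 0.0227 to 0.961), -0.018 after thinning and -0.056 to 0.106 with a library left out. Between PLAXAW and PLAXA, SOX2 was -0.037 with DESeq2 and relative log expression factors and -0.06 to 0.101 with a library left out, KLF4 was 0.062 with library totals and -0.048 to 0.012 with a library left out, and SUSD2 was 0.015 and -0.145 to 0.013. In aneuploid against euploid cells HSPA5 was 0.041 and SOX2 0.065, 0.066 and 0.065 with TPM.

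Gene lists whose test changed direction were past the threshold on neither side, and their medians follow. Imprinted genes in PLAXA against primed cells were at -0.123 with the strict filter, -0.039 with only both groups' libraries and -0.23 after thinning, in PLAXAW against primed cells at -0.167 after thinning, and between PLAXAW and PLAXA at -0.138 with the replicate block and -0.269 to -0.131 with a library left out. NF-kB genes were at 0.845 in PLAXAW against primed cells and -0.083 in aneuploid against euploid cells with the strict filter, and at -0.101 in the latter with only both groups' libraries. YAP-TEAD targets between PLAXAW and PLAXA were at 0.345 with only both groups' libraries, 0.348 with the replicate block and 0.276 to 0.355 with a library left out. With a library left out they were at -0.186 to 0.101 in PLAXA and 0.442 to 0.559 in PLAXAW against primed cells, BMP targets at -0.72 to 0 in PLAXA against primed cells, and in aneuploid against euploid cells autophagy at -0.042 to 0.07, apoptosis at -0.072 to 0.031 and core pluripotency at -0.142 to -0.086.

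Depth limits genes at 0 in a group to bounds, and the shallowest libraries, in PLAXA, held 5553544 and 5795600 counts. After thinning to the smallest total, 9222, 9641, 4889 and 3867 genes were called.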

Other observations

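The tests of copy gain, expression level and regional difference in a run of genes on chromosome 1, of other cells in the PLAXAW cultures, of fibroblasts and of feeder reads were chosen after the result was seen, as was the thinning that the test of depth uses, whose prediction was written before its own result. The test of a few genes taking the counts was set beforehand.

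A scan for runs of neighbouring genes in aneuploid against euploid PLAXAW cells found 217 genes on chromosome 1, from NAXD to DMAC1, with a median change of 0.53 (interquartile range 0.13 to 0.83), 77.9% of them above 0, against 0.08 over the 729 other genes of that chromosome. Its score of 12.5 exceeded the highest of 100 permutations of gene order, 4.91 (p = 0.0099, the smallest they can give). The permutations ignore neighbouring genes that vary together, and the euploid comparisons passed them as well, so that p is not specific to aneuploidy. In PLAXAW against PLAXA a run of 153 genes on X, from SHROOM4 to IRS4, scored -6.75 with a median of -0.38. In PLAXA against primed cells a run of 100 genes on chromosome 1, from NCS1 to MCAT, scored -6.42 with a median of -0.58. In aneuploid against euploid cells the next score, 8.56, was on chromosome 22.

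A gain of 1 copy of that block is a candidate explanation, since 3 copies over 2 give a log2 change of 0.58, but it was not tested independently. Among 21 genes of the block that differed by less than 0.25 (log2) in each comparison of the euploid groups the median was 0.578 (interquartile range 0.49 to 0.69), against 0.11 over 986 such genes elsewhere. The block was found by its high median in this same comparison, and the central 95% of 10000 random subsets of 21 block genes had medians of 0.24 to 0.76, so the value restates the observation. Expression level alone is argued against, as the highest score of the same scan over genes permuted within 20 bins of mean expression was 5.14, against 12.5 for the block. These permutations also break up neighbouring genes that vary together, so they do not bear on that. A shift of scale common to all genes was removed before each scan, so scaling was not tested. A regional difference between cultures unrelated to ploidy stays open, because the design has 1 aneuploid group, and the block's median in PLAXAW against PLAXA was 0.052. The aneuploid libraries gave 0.50 each, and RNA alone gives no copy number.

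Endoderm and fibroblast genes were lower in aneuploid cells, with 15 falling members in each list, and the primed, amnion, mesoderm and trophoblast lists fell as well. With an estimated correlation the endoderm list alone of these passed (camera, adjusted p = 0.0249), and the fibroblast, primed, amnion, mesoderm and trophoblast lists did not (0.0965 each). After all libraries were thinned to the smallest total, 26 of the 30 falling members were still called lower, so these calls did not need the greater depth of the aneuploid libraries. Thinning keeps the expected ratios between groups, and the 30 members were chosen by their calls. It therefore does not test any other effect of depth. Other, differentiating cells in the euploid PLAXAW cultures may contribute, and a loss of these transcripts in all cells may too. If a single other cell type had been lost, its own genes would fall alike, and the range over the 14 falling endoderm members with more than 3 counts in aneuploid cells was 5.27, from -0.28 for GATA4 to -5.54 for APOA1, but members that the main cells also express would fall less, so the test does not decide. Of the 17 endoderm genes tested, 4 are in another list, and 10 reached 1 CPM in aneuploid cells and 11 in primed cells. Of the 20 fibroblast genes 2 are in another list, and 16 and 18 did.

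The collagen genes COL1A1 and COL3A1 were high in PLAXA. No list of collagens was tested, and the fibroblast list, of which 13 members rose against primed cells, did not pass with an estimated correlation (adjusted p = 0.354). DCN and LUM both had 0 counts in PLAXA beside 180237 counts of COL1A1, which allows DCN at most 0.00166% of COL1A1. In euploid PLAXAW cells DCN was at 1.13% of COL1A1, and cells with that ratio would have left DCN counts. The test does not decide on marmoset fibroblasts, because both genes had been seen at 0 before and the ratio was not measured in fibroblasts. OGN, a proteoglycan of connective tissue, was high in PLAXA. A few genes taking most of the counts is argued against, since the 10 genes with the most counts held 6.25% and 6.56% of them in the PLAXA libraries. That share was not the test set beforehand, which was the median rise of the 13 rising fibroblast members. It was 3.3 with library totals and 3.5 with TMM, a move below the limit set for this explanation. The move is a shift of scale that all genes share, so that test does not decide. Reads of feeder cells of another organism may contribute, and the 13 members that rose do not decide it, since reads were not analysed here. The culture condition, known only as the label of the group, was not tested as a cause, nor was any biological explanation beyond those above.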
